A study of Mus musculus with 42 samples.

How the data were processed

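Gene expression was measured in mouse hepatocytes with single-colour Agilent arrays, 1 array per sample, in 42 samples. Per the labels, mice were left untreated or received a single whole-body X-ray dose of 3.8 Gy at 1 week of age. From 7 weeks they were fed either 95 kcal per mouse per week (AL) or 65 kcal per mouse per week (calorie restriction, CR). Hepatocytes were sampled at 7, 8, 10 and 40 weeks, which gives 14 groups of 3 arrays. The labels do not say that the 3 arrays of a group come from separate animals, so all p-values measure only the spread between these samples. The sex of the mice, the hour of collection and any fasting before collection are not given in the sources used here.

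Per the file headers and the submitters' processing notes, the deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold, for each of 62976 spots, the background-subtracted and detrended Cy3 intensity of 1 array, with no scaling between arrays. Raw foreground and local background median intensities and flags for spots well above background, saturated or nonuniform stand beside it. The deposited table of the submitters' processed values holds log2 values of the same arrays. Differences between arrays in that table had a slope of 1 and a correlation of 1 against those of the scaled log2 scanner intensities, and each probe was centred on its median over the 42 arrays. The column medians of that table lay between -0.2282 and 0.5142. How the submitters corrected background and scaled arrays beyond this is not given.

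From the processed intensities, log2 values were taken and the 75th percentile of each array was subtracted. The 3671 control spots and the spots marked nonuniform or an outlier were left out and the other spots of a probe were averaged, which gave 55681 probes, of which 198 lacked a value on some array and were not used. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which held for 30875 probes. The RefSeq accessions that the scanner files give for the probes were matched to gene symbols in the reference table, which named 27235 probes with 20660 symbols, and probes without a match were not used. Of 18620 named probes kept, the probe with the highest mean represented its gene, and 14368 genes were tested. For 3567 genes more than 1 probe was kept. Among 1576 named and called gene comparisons, 334 had more than 1 probe, and in 22 of these a further probe pointed the opposite way. Between 26663 and 31234 probes per array were well above background, and the number of arrays, 3 per group, limits the precision.

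Groups were compared with limma 3.58.1 in R 4.3.3. A single model with 1 mean per group was fitted to all 42 arrays, so all groups share 1 estimate of the spread, and eBayes moderated it. Comparisons were irradiated against nonirradiated arrays at each age and diet, CR against AL at each age and irradiation state, 40 against 8 weeks under AL, the means of the irradiation effect over 7 ages and diets and of the diet effect over 6 ages and irradiation states, and the interaction of diet and irradiation at each age. P-values were adjusted per comparison by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Values are log2 differences with the standard error of the fit (SE). Where a gene was well above background on no array of the dimmer group, its change is a lower bound, written as at least N-fold. It compares the mean of the brighter group with the mean of the dimmer group after raising each value to at least the lowest signal well above background on its array. Where this held for any group of a mean effect, an interaction or a difference between ages, the fitted value has no settled size.

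Lists of genes fixed before the data were examined, 38 in all, were tested with camera from limma at its preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison. They cover metabolic, hormonal and stress pathways of the liver, hepatocyte zones and markers of other cell types. The choice of groups, tests, lists, main settings and most alternatives was also made before the data were examined. Genes named in the text were chosen by a rule fixed with them: among called genes whose group values did not overlap (same sign in every age and group for the mean comparisons, no such condition for interactions) and that have an ordinary symbol, the 4 largest rises and falls of each comparison (8 for the mean comparisons), up to 4 called members of each list with the largest change, and 20 preset genes called or not. A few genes that the rule names are not reported here. The contrasts between ages of the diet effect and of the irradiation effect under CR were added after the data were seen, with the same rule.

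The alternatives were normexp background correction with an offset of 50 on the median signals, quantile normalization, the submitters' processed values, no filter on dim probes (20614 genes), slide as a fixed or a random block, comparisons within slides that hold both groups (a lone array is assumed to vary like the others), the replicate number as a block, only the compared groups in the fit, and each array left out in turn. The planned mean signal column is not in the files used here, so normexp used the median signal column. The arrays lay on 6 slides scanned as 2 batches, slides 1 to 4 (scan 1) and slides 5 and 6 (scan 2). Slide 1 held only 8-week arrays, 2 each of the nonirradiated AL and CR groups, with a higher spread of negative controls (SD 3.12 to 3.86) than the other slides, whose highest was 2.81 on slide 5. Leaving out slide 1, or single ages and groups from the mean comparisons, was added later. The correlation of arrays on the same slide was 0.122 over genes. No slide held both groups in the comparisons of ages, of CR with AL in nonirradiated mice at 40 weeks, and of CR with AL in irradiated mice at 10 weeks.

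The labels number the samples of each group 1 to 3 without saying what a number marks. The deviations of samples with the same number from their group means had correlations of 0.56, 0.344 and 0.365 between the nonirradiated CR and AL groups at 8 weeks, of 0.186, 0.124 and 0.224 between the same groups at 10 weeks and of 0.12, 0.104 and 0.174 between irradiated and nonirradiated CR groups at 10 weeks. In the other 12 comparisons at least 1 of the 3 correlations was 0.1 or lower. At 8 weeks the numbering coincides with the slides, since arrays 2 and 3 of the nonirradiated groups lay on slide 1. Only limma fits and camera were tested on simulated data (200 changed genes). A log2 change of 1 was recovered for 72% of genes for irradiation at 7 weeks and 70% for nonirradiated diet at 10 weeks. Recovery was 44.5% for the 40-week interaction and 99.5% and 97% for the mean irradiation and diet effects.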

Results

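Transcript levels were compared in hepatocytes of mice that had or had not received whole-body X-rays (3.8 Gy) at 1 week of age and were fed 95 (AL) or 65 (CR) kcal per week from 7 weeks. Hepatocytes are the metabolic cells of the liver. Each of the 14 groups had 3 arrays, and 14368 genes were tested. Correlations between arrays of the same group lay between 0.9746 and 0.9948 over probes, lowest in the irradiated AL group at 8 weeks. Changes are log2 differences ± SE with limma adjusted p-values, and n = 3 arrays per group unless a slide or array is left out.

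**Figure D1:**
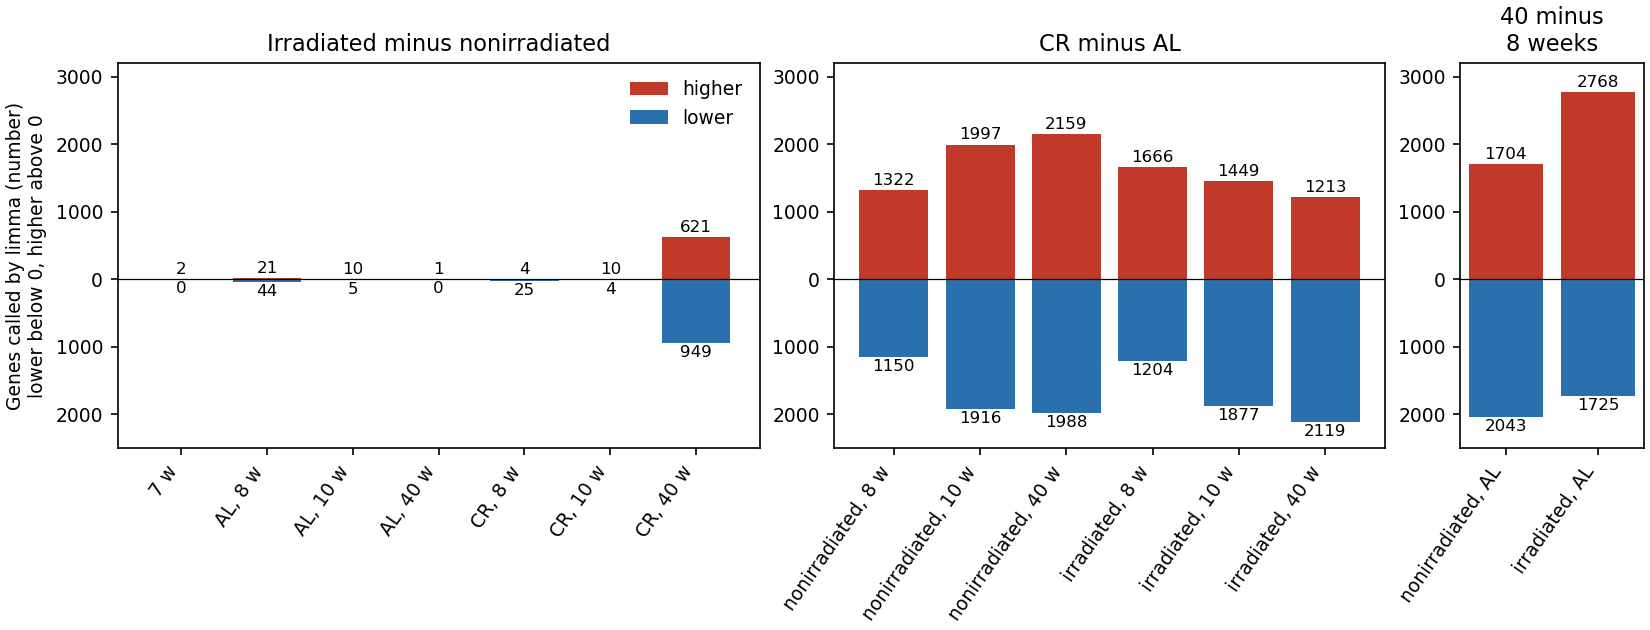
Numbers of genes called by limma as higher (red, above 0) or lower (blue, below 0) in irradiated against nonirradiated, CR against AL and 40-week against 8-week arrays, with 3 arrays per group. Among the irradiation comparisons the CR groups at 40 weeks had the most called genes, 621 higher and 949 lower, and each diet comparison had 1213 or more genes higher.

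At 7 weeks, 6 weeks after irradiation and before the diets, 2 genes were higher in irradiated hepatocytes and 0 lower. Igf2bp3, an RNA-binding protein of fetal tissues, was at least 6.81-fold higher (adjusted p = 0.0251). Ly6c1, a surface protein of endothelial and myeloid cells, rose by 1.33 ± 0.24 (adjusted p = 0.0481, a further probe by 0.47). Of 23 measured p53 target genes 0 were called over all genes and 0 when adjusted over the list alone (median 0.03, camera adjusted p = 0.196). Cdkn1a, the p53 target that encodes p21, differed by 1.62 ± 0.68 (adjusted p = 1) and Mdm2 by 0.10 ± 0.12 (adjusted p = 1). Of 31 interferon response genes 0 were called over all genes and 2 when adjusted over the list alone, all higher, with a median of 0.19 (camera adjusted p = 1.24e-06, adjusted p = 0.467 with an estimated correlation). No member of the fatty acid synthesis list (20 genes, median -0.47) or of the cell cycle list (25 genes, median 0.38) was called, over all genes or adjusted over the list alone. Both had a camera adjusted p of 1.24e-06 (adjusted p = 0.418 and 0.377 with an estimated correlation). The limma test left 607 genes at an unadjusted p under 0.05. All 6 arrays lay on slide 5, and list medians there were the same with slide as a block. Ly6c1 had an adjusted p of 0.0523 with slide as a block, 0.0623 within the slide and 0.0576 with no filter on dim probes, and Igf2bp3 one of 0.0681 with normexp. Without nonirradiated arrays 1 or 3 the interferon median was 0.30 or 0.11, and without array 2 the cell cycle median was 0.25. Igf2bp3 was lost without nonirradiated array 1 (0.184, at least 4-fold) or irradiated arrays 1 (0.106), 2 (0.313) or 3 (0.0612). Ly6c1 was lost without nonirradiated arrays 2 (0.268) or 3 (0.0686) or irradiated arrays 1 (0.197), 2 (0.313) or 3 (0.198). The count was 0 without any of the irradiated arrays, 1 without nonirradiated array 3, 0 with only these groups fitted and 5 with quantile normalization (3 higher, 2 lower).

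Under AL at 8 weeks, 21 genes were higher and 44 lower in irradiated hepatocytes. Ly6a, an interferon-inducible surface protein, rose by 1.81 ± 0.28 (adjusted p = 0.00221) and Oas1a, an antiviral enzyme, by 1.11 ± 0.21 (adjusted p = 0.0226). Fut4, a fucosyltransferase, was at least 3.77-fold lower (adjusted p = 0.0287). Oas1a was the only called member among 31 interferon response genes, over all genes and adjusted over the list alone (1 each), and the list had a median of 0.18 (camera adjusted p = 6.92e-05, adjusted p = 0.953 with an estimated correlation). Among 23 p53 target genes 0 were called over all genes and 1 was higher when adjusted over the list alone (median -0.11, camera adjusted p = 0.975). The slide block left 1 gene called and slide 6, with 3 irradiated arrays and 1 nonirradiated, 4. Ly6a (adjusted p = 0.126 and 0.123), Oas1a (0.2 and 0.213) and Fut4 (0.496 and 0.669) were not called, and the interferon median was 0.21 and 0.44. The p53 median was -0.05 with slide as a block and 0.00 within slide 6.

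Leaving out 1 array leaves 2 in its group. Without nonirradiated arrays 1, 2 or 3 limma called 1906, 7 and 9 genes. Without irradiated arrays 1, 2 or 3 it called 24, 12 and 855. Without nonirradiated array 1 no slide held both groups. Oas1a was lost without nonirradiated arrays 2 (adjusted p = 0.0893) or 3 (0.0584) or irradiated array 1 (0.069), with differences of 1.07, 1.17 and 1.01. The call of Fut4 ended without nonirradiated arrays 2 (0.0962) or 3 (0.151) or irradiated array 2 (0.126). The interferon median was 0.08 and 0.37 without nonirradiated arrays 1 and 3 and 0.32 without irradiated array 2. Quantile normalization called 118 genes higher and 135 lower and normexp 21 in all. Fut4 was lost with normexp (adjusted p = 0.571) and with slide as a random block (0.0626). Counts were 101 with no filter on dim probes, 8 with slide as a random block, 49 higher and 85 lower with the replicate block, 3 without slide 1 and 0 with only these groups fitted.

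Under AL at 10 weeks, 10 genes were higher and 5 lower after irradiation. The acyl-CoA thioesterase Acot1 rose by 1.99 ± 0.37 and its paralog Acot2 was at least 5.05-fold higher (adjusted p = 0.0172 each). Cyp8b1, the 12α-hydroxylase of bile acid synthesis, rose by 2.08 ± 0.39 (adjusted p = 0.0198), and the neutrophil chemokine Cxcl1 fell by 2.87 ± 0.59 (adjusted p = 0.0409). Of 8 neutrophil markers 0 were called over all genes and 5 were lower when adjusted over the list alone, with a median of -1.64 (camera adjusted p = 1.1e-06), which held with an estimated correlation (adjusted p = 0.0081). The acute phase list, 26 genes, had 0 calls over all genes and 12 lower adjusted over the list alone (median -0.44, camera adjusted p = 1.48e-12, adjusted p = 0.178 with an estimated correlation). Among 30 PPARα target and fatty acid oxidation genes 2 rose over all genes and 5 adjusted over the list alone (median 0.28, camera adjusted p = 1.71e-06, adjusted p = 0.331 with an estimated correlation). Saa1, an acute phase protein of the liver, lay at 9.89 to 11.01 in the nonirradiated arrays and at 5.73, 7.33 and 10.80 in the irradiated ones. At 8 and 40 weeks nonirradiated AL arrays had 3.80 to 5.72. Irradiated array 1 lay on slide 6 and the other 5 arrays on slide 2. The slide block left 2 genes called and slide 2 alone only 1. Acot1 (adjusted p = 0.0666 and 0.0822), Acot2 (0.192 and 0.186), Cyp8b1 (0.3 and 0.261) and Cxcl1 (0.3 and 0.261) were lost. With the block the 3 list medians were -1.23, -0.32 and 0.14.

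At 10 weeks under AL limma called 1, 50 and 72 genes without nonirradiated arrays 1, 2 or 3. It called 2 and 113 without irradiated arrays 1 or 3. Without irradiated array 1 the adjusted p was 0.275 for Acot1, Acot2, Cyp8b1 and Cxcl1 (1.44, 1.79 and -2.76 without Acot2, which has only a bound). Without nonirradiated array 1 it was 0.112, 0.0819, 0.115 and 0.177 (2.04, 2.09 and -1.97). Without irradiated arrays 1 or 3 Acot2 was at least 2.98-fold or 8.22-fold higher and the PPARα median was 0.14 or 0.43. Cyp8b1 was also lost without nonirradiated array 3 (0.0573) or irradiated array 2 (0.0589), and Cxcl1 without irradiated array 2 (0.0885), with no filter on dim probes (0.0619) or with the replicate block (0.0627). Acot2 had an adjusted p of 0.606 with normexp. Counts were 34 with normexp (15 higher, 19 lower), 23 with quantile normalization, 8 with no filter on dim probes and 0 with only these groups fitted.

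At 40 weeks under AL, 1 gene was called after irradiation and 647 had an unadjusted p under 0.05 in limma. Cd36, a fatty acid transporter, rose by 1.92 ± 0.34 (adjusted p = 0.0446). Of 26 endoplasmic reticulum stress genes 0 were called over all genes and 6 were higher when adjusted over the list alone (median 0.37, camera adjusted p = 5.07e-08, adjusted p = 0.563 with an estimated correlation). Their median was 0.31 with slide as a block and within slides. Cd36 differed by 1.36 with slide as a block (adjusted p = 0.983) and within slide 3 (adjusted p = 0.98), which held 1 irradiated array against 3, and 2 and 4 genes were called. It was lost with quantile normalization (0.0686), no filter (0.0789), slide as a random block (0.175), the replicate block (0.218), or without nonirradiated arrays 2 (0.487) or 3 (0.0754) or irradiated arrays 2 (0.282) or 3 (0.475). Limma called 0 genes in the first 4 of these settings, with only these groups fitted and without nonirradiated array 2 or irradiated arrays 2 or 3, 2 without nonirradiated array 3, and 3 without irradiated array 1 or with normexp.

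Under CR at 8 weeks, 4 genes were higher and 25 lower in irradiated hepatocytes. Oas1a rose by 1.01 ± 0.21 (adjusted p = 0.0312), and Nr4a1, an immediate early nuclear receptor, fell by 2.89 ± 0.64 (adjusted p = 0.0406). The cholesterol synthesis list, 23 genes, had 0 calls over all genes and 1 higher adjusted over the list alone (median 0.41, camera adjusted p = 2.56e-08, adjusted p = 0.637 with an estimated correlation). That median was 0.26 with slide as a block and 0.25 within slides. Limma called 0 genes with slide as a block and 20 within slide 5, which held 1 array of each group, and Oas1a (adjusted p = 0.296 and 0.422) and Nr4a1 (0.506 and 0.14) were not among them. Nor were they with normexp (0 genes; 0.0775 for each) or slide as a random block (6 genes; 0.0742 and 0.0996). The counts were 583 (no slide then held both groups), 12 and 5 without nonirradiated arrays 1, 2 or 3 and 14, 13 and 4 without irradiated ones. Oas1a was lost without nonirradiated arrays 2 (0.225) or 3 (0.166) or irradiated arrays 1 (0.18), 2 (0.0625) or 3 (0.142). Nr4a1 was lost without nonirradiated arrays 2 (0.0687) or 3 (0.178) or irradiated arrays 1 (0.184) or 2 (0.212). Counts were 12 higher and 22 lower with quantile normalization, 111 with no filter, 59 with the replicate block and 1 with only these groups fitted.

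Under CR at 10 weeks, 10 genes were higher and 4 lower. The transcription factor Dmrta1 was at least 8.96-fold higher (adjusted p = 0.00345). Of 23 cholesterol synthesis genes 0 were called over all genes and 5 were lower when adjusted over the list alone (median -0.42, camera adjusted p = 1.54e-05, adjusted p = 0.845 with an estimated correlation). The 20 genes expressed more in male than in female mouse liver had 0 calls over all genes and 0 adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.00177, 0.087 with normexp, adjusted p = 0.845 with an estimated correlation). Limma called 3 genes each with slide as a block and within slide 3, which held 3 irradiated arrays and 1 nonirradiated. Dmrta1 was lost (adjusted p = 0.306 and 0.306), and the list medians were -0.54 and 0.41. The replicate block left 4 genes. Counts without 1 array were 0 and 1 for nonirradiated arrays 1 and 2, and 2, 8 and 7 for irradiated arrays 1, 2 and 3. Dmrta1 was lost without nonirradiated arrays 1 (0.0697) or 2 (0.0504) or irradiated array 1 (0.0594). Other counts were 20 higher and 13 lower with quantile normalization, 3 with normexp, 3 with slide as a random block and 0 with only these groups fitted.

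At 40 weeks under CR, 621 genes were higher and 949 lower in irradiated than in nonirradiated hepatocytes. Genes more expressed in male than female mouse liver were among those that rose. The sulfotransferase Sult5a1 rose by 3.41 ± 0.32 (adjusted p = 5.39e-08) and Hsd3b5, a steroid dehydrogenase of male liver, by 3.53 ± 0.70 (adjusted p = 0.00137). The fatty acid elongase Elovl3 rose by 3.06 ± 0.55 (adjusted p = 0.000525). Of 20 male-biased genes 11 rose over all genes and 13 adjusted over the list alone, and 0 fell (median 1.73, camera adjusted p = 1.69e-13, adjusted p = 0.166 with an estimated correlation). Cux2, a transcription factor of female liver, was at least 13.5-fold lower (adjusted p = 5.38e-05), and the female-biased cytochromes Cyp2b9 and Cyp2b13 differed by -3.77 ± 0.91 (adjusted p = 0.0077) and -3.38 ± 0.80 (adjusted p = 0.00661). The female-biased list as a whole did not pass, with 2 of 19 genes higher and 3 lower, 2 and 5 adjusted over the list alone (median -0.57, camera adjusted p = 0.225), although its adjusted p was 0.0432 without nonirradiated array 1.

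In the same groups the adaptor Stap1 was at least 12-fold higher (adjusted p = 3.54e-06), and Bhmt, which remethylates homocysteine, rose by 2.61 ± 0.22 (adjusted p = 8.77e-09). Of 31 interferon response genes 14 rose and 0 fell (16 and 1 adjusted over the list alone), among them Ifit1 by 1.39 ± 0.30 (median 0.70, camera adjusted p = 1.44e-09, adjusted p = 0.6 with an estimated correlation). Of 11 erythroid and blood markers 2 rose, over all genes and adjusted over the list alone (median 0.73, camera adjusted p = 0.000926, adjusted p = 0.952 with an estimated correlation). Without irradiated array 2 the erythroid list had a median of 0.26 and an adjusted p of 0.0772.

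All 6 of these arrays lay on slide 4, where the list medians were the same, and limma called 1739 genes with slide as a block and 1744 within the slide. The irradiated arrays differed from each other, with Cyp2b9 at 0.67, -3.16 and -5.37 and Hsd3b5 at 2.87, 5.99 and 5.84 on the normalized log2 scale for arrays 1, 2 and 3. The fit of these 2 groups alone called 11 genes. Without irradiated array 3 limma called 408 genes, without nonirradiated array 2 it called 505 and without nonirradiated array 1 it called 959. Cyp2b9 had an adjusted p of 0.143 without irradiated array 3 and 0.0609 without nonirradiated array 2, and Cyp2b13 one of 0.127 without irradiated array 3. Cux2 was at least 30.4-fold and 7.39-fold lower without nonirradiated arrays 1 and 2, and Stap1 at least 18.5-fold higher without irradiated array 1.

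**Figure D2:**
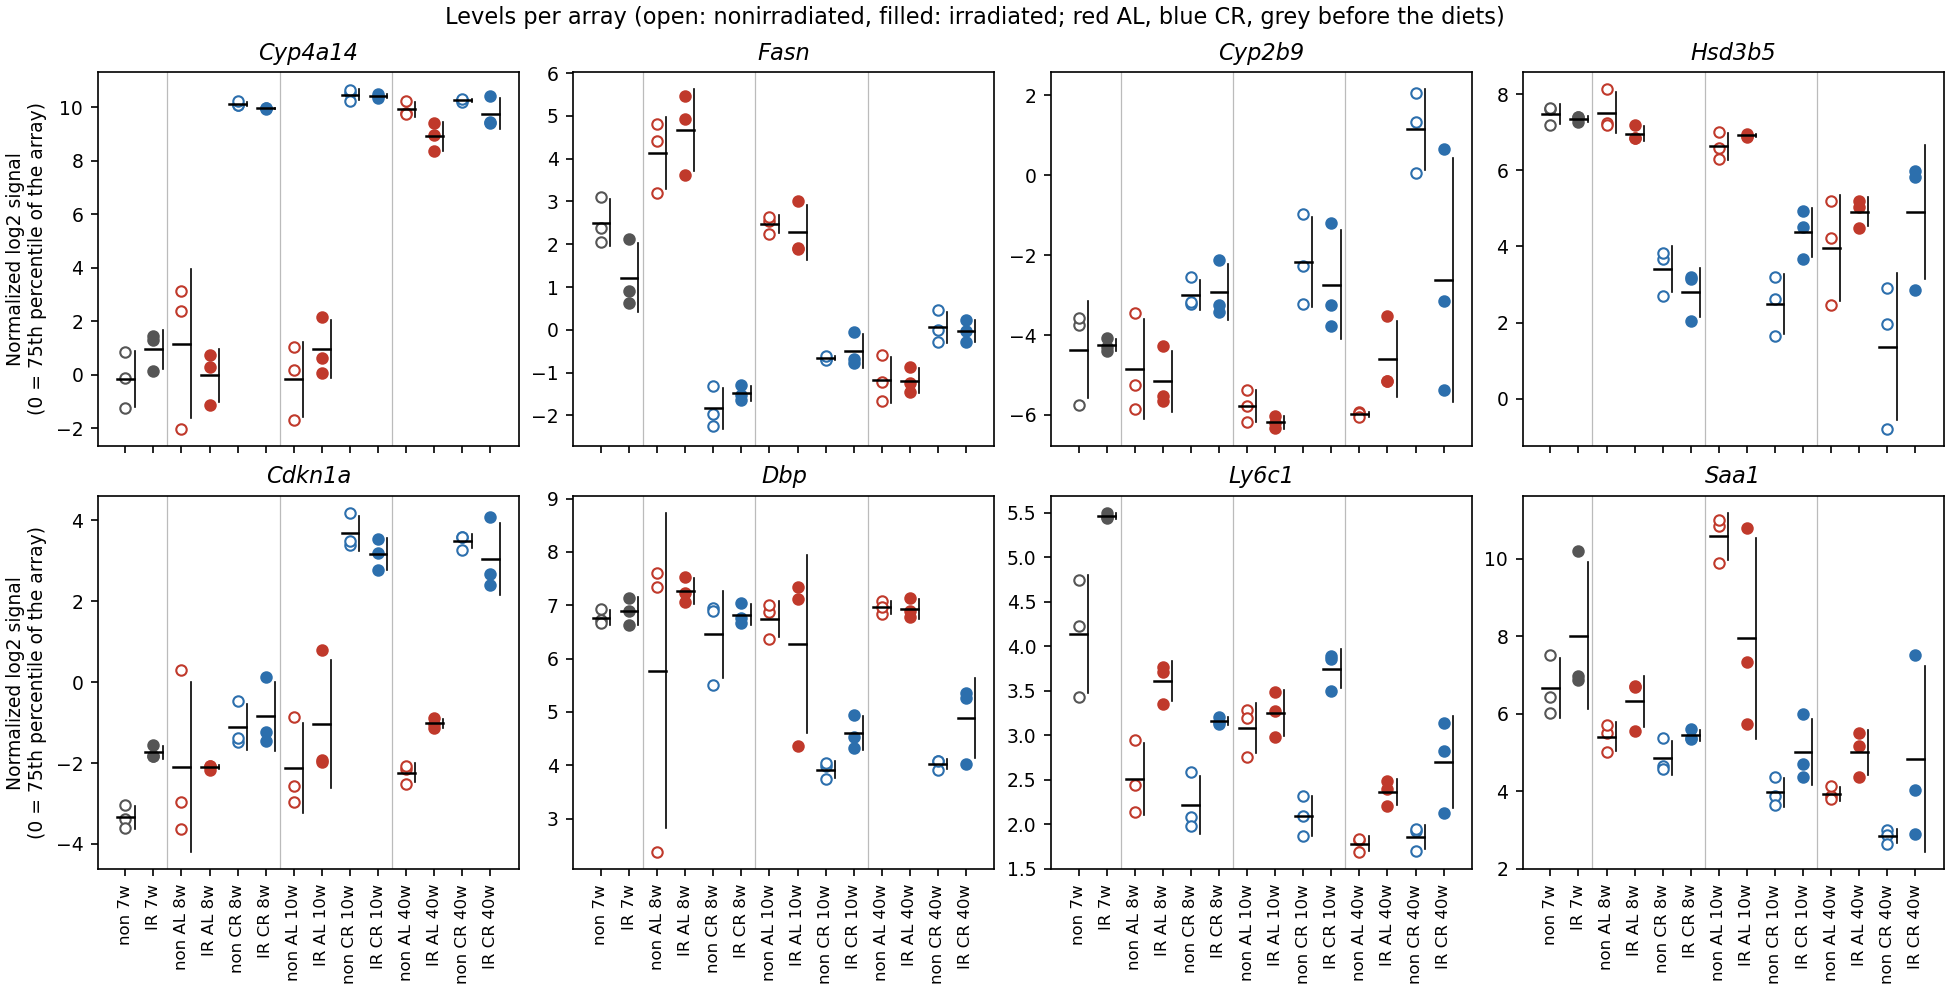
Normalized log2 levels of 8 genes on each of the 42 arrays by group, with 0 at the 75th percentile of the array. Points are arrays, horizontal lines group means and vertical lines 1 SD to either side. Cyp4a14 lies between -2.01 and 3.14 in AL arrays at 8 and 10 weeks and between 8.35 and 10.64 in all others after 7 weeks.

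Averaged over the 7 pairs of groups, irradiation raised 247 genes and lowered 244. Of these 491 genes, 162 had the same sign in all 7 pairs. Ly6c1 rose by 0.95 ± 0.09 (adjusted p = 3.05e-07), Oas1a by 0.66 ± 0.08 (adjusted p = 1.31e-05) and Sult5a1 by 0.86 ± 0.12 (adjusted p = 9.77e-05). These 3 kept their call under every setting run, but a further Ly6c1 probe rose by 0.12. The p53 target Phlda3 rose by 0.47 ± 0.10 (adjusted p = 0.00828). It was the only target called among 23, over all genes and adjusted over the list alone. The list's median was -0.02 against an upward camera test (adjusted p = 0.89). Mdm2 differed by -0.01 ± 0.05 (adjusted p = 0.95) and Cdkn1a by 0.46 ± 0.26 (adjusted p = 0.29). Of 31 interferon response genes 9 rose, 12 adjusted over the list alone (median 0.20, camera adjusted p = 6.72e-11, 0.292 with an estimated correlation). Of 20 male-biased genes 5 rose, 11 adjusted over the list alone (median 0.27, camera adjusted p = 2.24e-08, 0.292 with an estimated correlation). Their median was above 0 in 5 of 7 pairs and 1.73 under CR at 40 weeks. Of 19 female-biased genes 4 rose, 5 adjusted over the list alone, with a median of -0.02 against an upward camera test (adjusted p = 0.0186, adjusted p = 0.466 with an estimated correlation). That list was lost with normexp (0.0848), with slide as a block (median 0.01, 0.378), within slides (median 0.00, 0.466) or without CR array 1 at 40 weeks, nonirradiated (0.0543) or irradiated (0.0576). Of 22 endothelial and 11 erythroid markers 0 were called and 6 and 1 rose adjusted over the list alone. Medians were 0.15 and 0.23 (camera adjusted p = 6.52e-06 and 0.000628, 0.608 and 0.509 with an estimated correlation).

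For the mean irradiation effect limma called 15 genes with slide as a block and 23 within slides. Phlda3 was lost (adjusted p = 0.251 and 0.28). The interferon and male-biased medians were 0.12 and 0.31 with the block and 0.10 and 0.33 within slides (p53 targets 0.06 each, endothelial 0.18 and 0.17, erythroid 0.27 and 0.25). Limma called 185 genes with slide as a random block, 86 without slide 1, 147 without the CR groups at 40 weeks, 235 higher and 67 lower without the 8-week groups and 321 with no filter. Without 1 array the count was 313 for irradiated CR array 1 at 10 weeks, 322 and 1106 for nonirradiated CR arrays 3 and 1 at 8 weeks, and 324 and 1003 for nonirradiated AL arrays 1 and 3 at 10 weeks. It was 741 for irradiated CR array 1 at 40 weeks and 1368 for nonirradiated AL array 1 at 8 weeks. For the 1106 and 1368 no slide held both 8-week groups of that diet.

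After 1 week of diet, at 8 weeks of age, CR raised 1322 and lowered 1150 genes in nonirradiated hepatocytes and raised 1666 and lowered 1204 in irradiated ones. Fatty acid oxidation genes rose: the PPARα-induced hydroxylases Cyp4a14 and Cyp4a10 by 8.96 ± 0.79 and 6.25 ± 0.34 in nonirradiated (adjusted p = 1.01e-09 and 3.15e-14) and by 9.97 ± 0.79 and 7.63 ± 0.34 in irradiated mice (adjusted p = 1.14e-10 and 1.83e-16). Of 30 PPARα target and fatty acid oxidation genes 24 and 27 rose in nonirradiated and irradiated mice, 25 and 27 adjusted over the list alone (medians 1.08 and 1.41, camera adjusted p = 5.91e-26 and 4.84e-30). Lipid synthesis genes fell. Fatty acid synthase, Fasn, changed by -5.97 ± 0.42 and -6.15 ± 0.42 (adjusted p = 1.13e-11 and 6.08e-12). Squalene epoxidase, Sqle, changed by -5.56 ± 0.61 and -3.15 ± 0.61 (adjusted p = 7.38e-08 and 0.000317). Of 20 fatty acid synthesis genes 17 and 16 fell, 19 and 17 adjusted over the list alone (medians -2.30 and -2.71, camera adjusted p = 2.15e-26 and 9.14e-25). Of 23 cholesterol synthesis genes 21 and 19 fell, 22 and 19 adjusted over the list alone (medians -2.22 and -1.82, camera adjusted p = 9.56e-32 and 2.03e-19).

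In the same comparisons, Cidec, a protein of lipid droplets, rose by 3.34 ± 0.58 and 3.45 ± 0.58. Of 18 lipid droplet and steatosis genes 9 rose in each, with 1 and 2 lower (13 and 11 higher, 2 lower each, adjusted over the list alone; medians 1.01 and 0.95, camera adjusted p = 0.000158 and 0.00094). Of 19 female-biased genes 9 and 10 rose (9 and 11 adjusted over the list alone, medians 1.62 and 1.38, camera adjusted p = 1.64e-06 and 3.99e-06). Hsd3b5 fell by 4.11 ± 0.70 and 4.16 ± 0.70. Of 20 male-biased genes 6 and 8 fell (7 and 9 adjusted over the list alone, medians -0.54 and -0.77, camera adjusted p = 0.000652 and 5.06e-05; adjusted p = 0.404 and 0.392 with an estimated correlation). Cyp2b10, the marker of the xenobiotic receptor CAR, rose by 5.00 ± 0.81 and 3.41 ± 0.81. Of 22 xenobiotic response genes 12 and 14 rose and 3 and 2 fell (13 and 15 higher, 3 lower each, adjusted over the list alone; medians 1.32 and 1.36, camera adjusted p = 8.59e-09 and 1.18e-08). These lists held with an estimated correlation except the male-biased one. The adjusted p was 0.00773 for the PPARα and both synthesis lists in nonirradiated mice, where lipid droplets had 0.0226, female-biased genes 0.013 and xenobiotic response 0.0202. The values in irradiated mice lay between 0.00612 and 0.0462. Of 25 cell cycle genes 10 and 12 fell (12 and 14 adjusted over the list alone, medians -0.79 and -0.96, camera adjusted p = 2.07e-06 and 3.77e-07; adjusted p = 0.0736 and 0.0462 with an estimated correlation).

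Limma called 2097 genes with slide as a block in nonirradiated and 2312 in irradiated mice at 8 weeks, and within slides 1771 and 2143. The medians of PPARα targets were 1.06 and 1.41 with slide as a block and 1.02 and 1.43 within slides, those of fatty acid synthesis -2.26 and -2.65, then -2.14 and -2.75, and those of male-biased genes -0.52 and -0.73, then -0.24 and -0.81. Without slide 1 the nonirradiated count was 708, and with only the compared groups fitted the counts were 528 and 1271. Cdkn1a differed by 0.99 ± 0.68 and 1.26 ± 0.68 (adjusted p = 0.368 and 0.207), and by 2.19 (adjusted p = 0.0126) in nonirradiated mice without AL array 2. The male-biased median there was -0.31 without CR array 1.

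At 10 weeks, CR raised 1997 and lowered 1916 genes in nonirradiated and raised 1449 and lowered 1877 in irradiated hepatocytes. Cyp4a14 rose by 10.63 ± 0.79 and 9.45 ± 0.79 (adjusted p = 1.48e-11 and 6.77e-10). Acot2 was at least 159-fold higher in nonirradiated mice and rose by 4.23 ± 0.47 in irradiated ones. Of 30 PPARα target genes 28 and 24 rose, 28 and 27 adjusted over the list alone (medians 1.75 and 1.15, camera adjusted p = 1.05e-28 and 1.64e-24). Fasn changed by -3.14 ± 0.42 and -2.77 ± 0.42 and Sqle by -2.40 ± 0.61 and -3.94 ± 0.61. Of 20 fatty acid synthesis genes 14 and 13 fell (15 and 13 adjusted over the list alone, medians -1.26 and -1.05, camera adjusted p = 1.36e-09 and 5.87e-08; adjusted p = 0.113 and 0.158 with an estimated correlation). Of 23 cholesterol synthesis genes 16 and 17 fell and 1 and 0 rose (17 and 18 adjusted over the list alone, medians -1.36 and -1.53, camera adjusted p = 1.87e-08 and 7.35e-14; adjusted p = 0.221 and 0.109 with an estimated correlation). Of 18 lipid droplet genes 11 and 8 rose and 2 fell in each (13 and 9 higher adjusted over the list alone, medians 1.48 and 0.96, camera adjusted p = 3.76e-06 and 2.43e-05).

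Male-biased genes were lower and female-biased genes higher at 10 weeks. Moxd1, a monooxygenase-like protein, was at least 507-fold lower in nonirradiated mice and fell by 6.35 ± 1.08 in irradiated ones, and Hsd3b5 fell by 4.14 ± 0.70 and 2.55 ± 0.70. Of 20 male-biased genes 15 and 12 fell and 1 and 0 rose (16 and 14 adjusted over the list alone, medians -1.53 and -0.97, camera adjusted p = 6.63e-08 and 6.82e-06; adjusted p = 0.15 and 0.27 with an estimated correlation). Of 19 female-biased genes 13 rose and 1 fell in each (13 and 14 adjusted over the list alone, medians 1.99 and 1.71, camera adjusted p = 3.76e-06 and 5.17e-08). Cyp2b10 rose by 8.30 ± 0.81 and 5.75 ± 0.81. Of 22 xenobiotic response genes 15 rose in each and 1 and 3 fell, over all genes and adjusted over the list alone (medians 1.13 and 1.00, camera adjusted p = 1.07e-08 and 8.61e-08). The lists of PPARα targets, lipid droplets, female-biased genes and xenobiotic response held with an estimated correlation, with adjusted p-values of 0.0122, 0.0142, 0.0265 and 0.0265 in nonirradiated mice and between 0.0141 and 0.0464 in irradiated mice.

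Cdkn1a rose by 5.82 ± 0.68 (adjusted p = 1.01e-07) and 4.21 ± 0.68 (adjusted p = 3.21e-05) with CR at 10 weeks. The clock gene Arntl rose by 4.48 ± 0.92 and 3.07 ± 0.92 (adjusted p = 0.000414 and 0.0151). Irradiated AL array 3 had a clock score (Arntl minus the mean of Dbp and Nr1d1) of 0.18 against -6.56 and -6.52 in its group and -0.21 to 1.04 in irradiated CR arrays. The list of 20 clock genes had members going both ways, 5 higher and 6 lower in nonirradiated mice and 5 and 4 in irradiated ones (5 and 8, then 5 and 4, adjusted over the list alone; medians -0.67 and -0.28, camera adjusted p = 0.453 and 0.902). Of 26 endoplasmic reticulum stress genes 16 and 18 fell and 1 rose in each (16 and 19 adjusted over the list alone, medians -1.10 and -0.93, camera adjusted p = 1.36e-09 and 7.37e-12; adjusted p = 0.15 and 0.109 with an estimated correlation). Of 31 interferon response genes 15 fell in each and 2 and 0 rose (16 lower adjusted over the list alone, medians -0.71 and -0.64, camera adjusted p = 5.82e-06 and 1.75e-05; adjusted p = 0.291 and 0.329 with an estimated correlation). Cxcl1 differed by -6.74 ± 0.59 and -3.21 ± 0.59 and Saa1 by -6.61 ± 0.91 and -2.93 ± 0.91. Nonirradiated AL arrays had Saa1 at 9.89 to 11.01, against 5.01 to 5.72 at 8 weeks. Of 8 neutrophil markers 5 and 3 fell, over all genes and adjusted over the list alone (medians -2.67 and -0.96, camera adjusted p = 0.00109 and 0.139; adjusted p = 0.0715 and 0.393 with an estimated correlation). Without irradiated AL array 1 the list in irradiated mice had an adjusted p of 0.0478. There 6 of 22 endothelial markers rose (6 adjusted over the list alone, median 0.35, camera adjusted p = 0.0019) and 7 of 22 Kupffer cell and macrophage markers fell (8 adjusted over the list alone, median -0.85, camera adjusted p = 0.000143), with adjusted p = 0.493 and 0.378 with an estimated correlation. Without irradiated AL array 3 the Kupffer cell median was -0.46.

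At 10 weeks limma called 3693 genes in nonirradiated mice with slide as a block, 3726 within slides and 2164 with only these groups fitted. In irradiated mice it called 599 with slide as a block, where no slide held both groups. That block ended the irradiated calls of Fasn (adjusted p = 0.0694), Hsd3b5 (0.702), Cyp2b10 (0.0726), Cdkn1a (0.0647), Arntl (0.288) and Saa1 (0.263), while Cyp4a14, Acot2, Sqle, Moxd1 and Cxcl1 were still called. List medians with that block were 1.07 for PPARα targets, 0.99 for lipid droplets, 1.26 for female-biased, -1.16 for male-biased, -1.02 for interferon, -1.52 for neutrophil, -1.17 for Kupffer cell and 0.20 for endothelial genes (the last with an adjusted p of 0.349). In nonirradiated mice the PPARα median was 1.65 with slide as a block and within slides. In irradiated mice, Hsd3b5 was lost without CR array 2 (0.0524), Arntl without CR array 2 (0.0513) or AL arrays 1 (0.075) or 2 (0.0955). Saa1 was lost there without CR arrays 1 (0.0643) or 3 (0.0726) or AL array 3 (0.23) or with slide as a random block (0.0577).

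**Figure D3:**
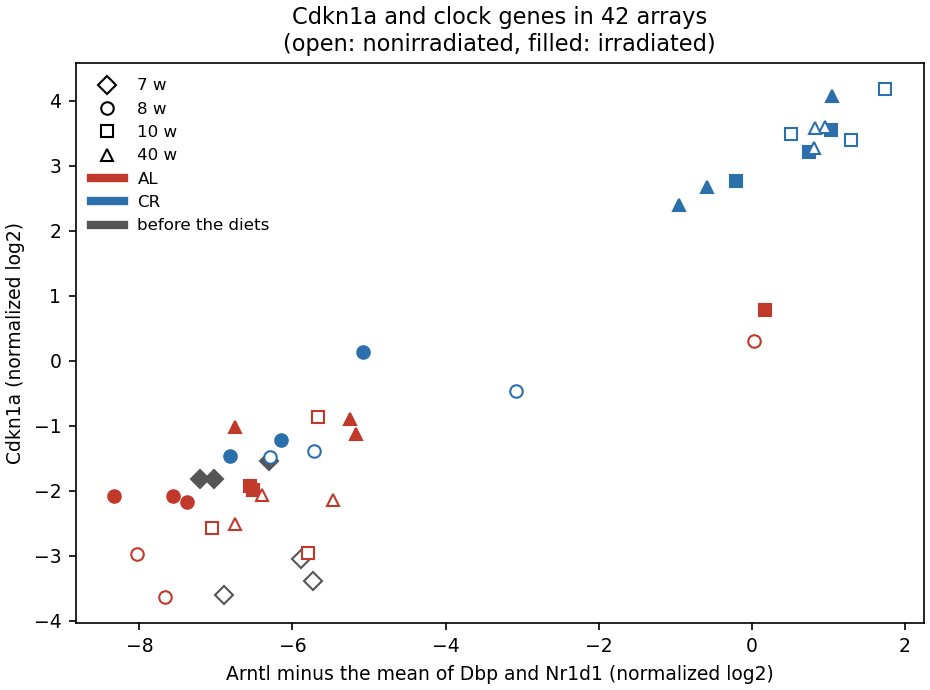
Cdkn1a against the clock score on each of 42 arrays (normalized log2). Cdkn1a lies between 2.39 and 4.19 on CR arrays at 10 and 40 weeks and between -3.64 and 0.79 on all others.

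**Figure D4:**
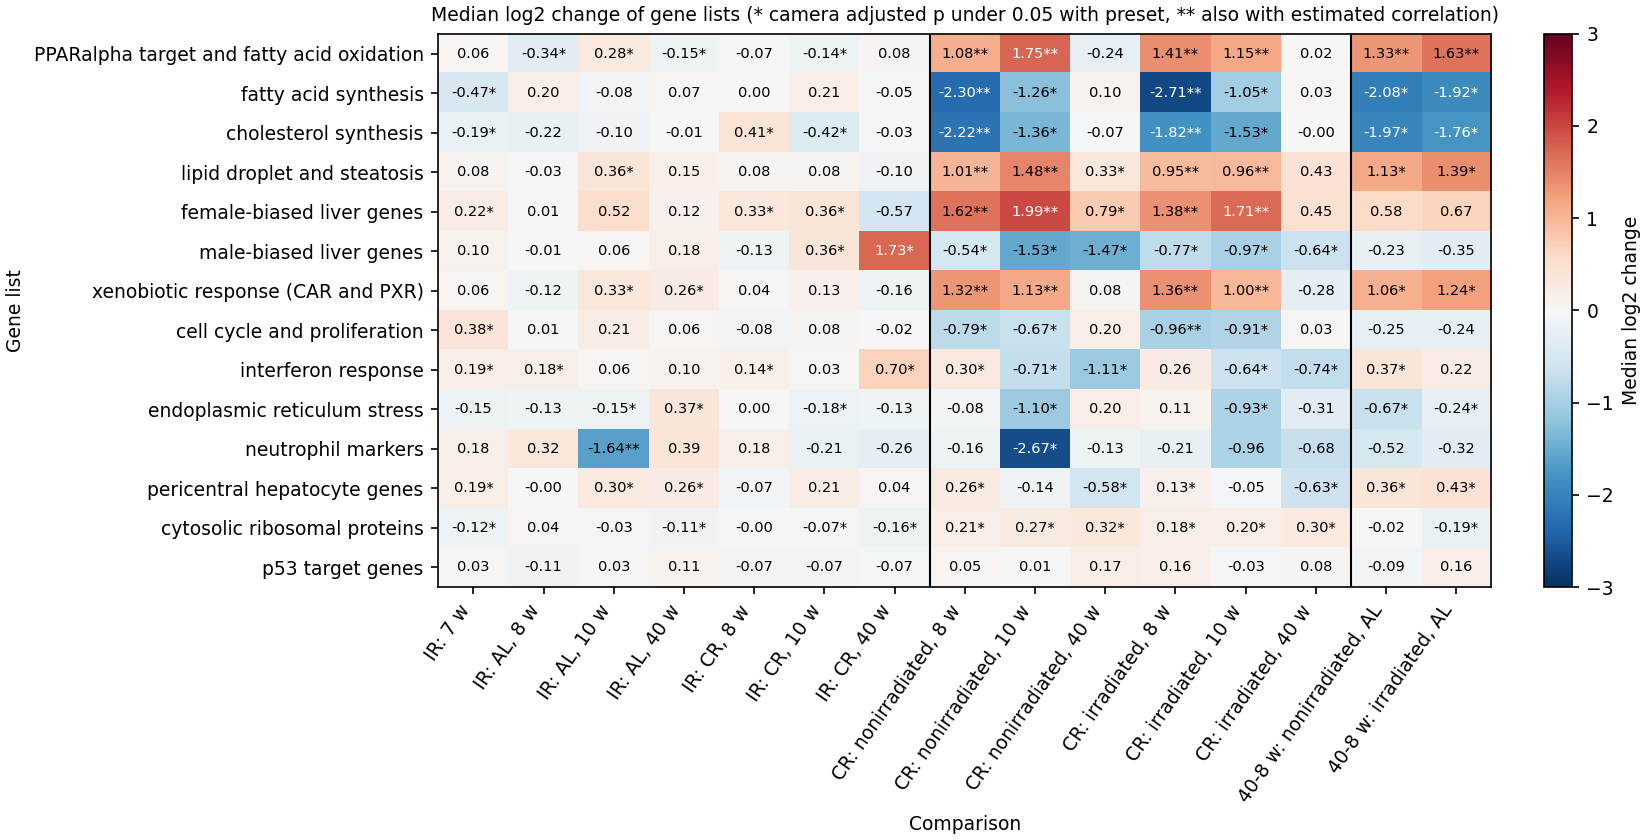
Median log2 difference of 14 gene lists (rows) in each comparison (columns), with 1 asterisk for a camera adjusted p under 0.05 and a pair for those that also pass with an estimated correlation. PPARα targets have medians of 1.08, 1.75, 1.41 and 1.15 with CR at 8 and 10 weeks and -0.24 and 0.02 at 40 weeks.

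At 40 weeks, CR raised 2159 and lowered 1988 genes in nonirradiated and raised 1213 and lowered 2119 in irradiated hepatocytes. Cyp4a14 differed by 0.34 ± 0.79 and 0.84 ± 0.79 (adjusted p = 0.796 and 0.469). Of 30 PPARα target genes 5 and 4 were higher and 7 and 3 lower (6 and 6 higher, 8 and 3 lower adjusted over the list alone; medians -0.24 and 0.02, camera adjusted p = 0.34 and 0.325, with a positive mean beside the negative median in nonirradiated mice). Of 20 fatty acid synthesis genes 5 and 3 were higher (3 and 2 adjusted over the list alone, medians 0.10 and 0.03, camera adjusted p = 0.374 and 0.276). Of 23 cholesterol synthesis genes 3 and 2 were higher and 4 and 1 lower (4 and 1 higher, 4 and 1 lower adjusted over the list alone; medians -0.07 and -0.001, camera adjusted p = 0.897 and 0.459). Of 18 lipid droplet genes 6 rose and 2 fell in each (7 higher, 2 and 3 lower adjusted over the list alone; medians 0.33 and 0.43, camera adjusted p = 0.0292 and 0.172; adjusted p = 0.358 and 0.91 with an estimated correlation). Cdkn1a rose by 5.72 ± 0.68 and 4.07 ± 0.68 (adjusted p = 2.17e-07 and 0.000119) and Pdk4, a kinase that restrains glucose oxidation, by 4.48 ± 0.65 and 4.93 ± 0.65. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 4.94 ± 0.76 and 2.83 ± 0.76 (adjusted p = 9.96e-06 and 0.00796).

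In nonirradiated mice at 40 weeks Cyp2b9 was at least 140-fold higher with CR (adjusted p = 6.35e-07), the lipoprotein receptor Vldlr rose by 4.91 ± 0.48 and Cd36 by 2.84 ± 0.34. In irradiated mice Cyp2b9 differed by 1.98 ± 0.91 (adjusted p = 0.111), Cd36 by -0.33 ± 0.34 (adjusted p = 0.519) and Vldlr by 1.92 ± 0.48 (adjusted p = 0.00474). Of 20 male-biased genes 14 and 7 fell and 0 and 1 rose (16 and 10 lower adjusted over the list alone, medians -1.47 and -0.64, camera adjusted p = 2.78e-11 and 0.0459; adjusted p = 0.174 and 0.91 with an estimated correlation). Of 19 female-biased genes 8 and 2 rose and 2 and 0 fell, over all genes and adjusted over the list alone (medians 0.79 and 0.45, camera adjusted p = 0.0164 and 0.272; adjusted p = 0.358 and 0.91 with an estimated correlation). Interferon response genes were lower with CR, Isg15 by -2.41 ± 0.26 and -1.51 ± 0.26. Of the 31 members 21 and 15 fell and 1 and 2 rose (22 and 17 adjusted over the list alone, medians -1.11 and -0.74, camera adjusted p = 4.71e-12 and 0.000229; adjusted p = 0.196 and 0.91 with an estimated correlation). Of 22 markers of liver endothelial cells 10 and 4 rose and 0 fell (12 and 4 adjusted over the list alone, medians 0.54 and 0.23, camera adjusted p = 0.000568 and 0.0459; adjusted p = 0.959 and 0.91 with an estimated correlation), among them the hyaluronan receptor Lyve1 by 1.62 ± 0.39 and 2.14 ± 0.39. Lgr5, a Wnt pathway gene of hepatocytes around the central vein, fell by 1.58 ± 0.37 and 2.28 ± 0.37. Of 19 pericentral genes 11 and 8 fell (11 and 12 lower adjusted over the list alone, medians -0.58 and -0.63, camera adjusted p = 0.000244 and 0.000229; adjusted p = 0.17 and 0.14 with an estimated correlation).

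No slide held both nonirradiated groups at 40 weeks, and limma called 1076 genes there with slide as a block. The medians of male-biased, female-biased and interferon genes were -1.56, 1.00 and -1.26, those of PPARα targets, fatty acid synthesis, cholesterol synthesis, lipid droplets and endothelial markers 0.01, 0.29, 0.39, 0.39 and 0.62. The female-biased list had an adjusted p of 0.0527, and Lgr5 (adjusted p = 0.333) and Lyve1 (0.128) were lost. The lipid droplet list was lost without nonirradiated AL array 3 (0.0921). In irradiated mice slide 4 held both groups, and limma called 2595 genes with slide as a block, 2633 within the slide and 806 with only these groups fitted. The male-biased, female-biased, interferon and endothelial medians within the slide were -0.68, 0.32, -0.73 and 0.23. The endothelial list was lost there (adjusted p = 0.0511), with normexp (0.15), no filter (0.126) or the replicate block (0.0611), and without irradiated CR arrays 1 (0.176) or 2 (0.151) or irradiated AL array 2 (0.121). The irradiated count was 1739 without CR array 3, where Cyp2b9 had an adjusted p of 0.0103, and 0.0312 with normexp. Without irradiated CR array 1 the cholesterol synthesis list rose (median 0.42, adjusted p = 0.0268) and Cyp7a1 (0.0825), Vldlr (0.0629) and the male-biased list (0.428) were lost. That list was also lost without irradiated AL array 3 (0.148) or with the replicate block (0.0633), and the female-biased list in nonirradiated mice without CR array 2 (0.0528).

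Averaged over the 6 pairs of groups, CR raised 3366 genes and lowered 3416, and 2414 of these 6782 genes had the same sign in all 6 pairs. Cyp4a14 (6.70 ± 0.32), Cyp2b10 (5.14 ± 0.33), Cdkn1a (3.68 ± 0.28) and Acot1 (3.58 ± 0.15) rose and Hsd3b5 (-2.93 ± 0.29) fell. Their adjusted p-values were 6.87e-10 or lower. Of 30 PPARα target genes 28 rose, over all genes and adjusted over the list alone (median 0.85, camera adjusted p = 3.3e-22, 0.0153 with an estimated correlation). Limma called 4232 genes with slide as a block, and the PPARα median was 0.93.

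Interaction tests of irradiation and diet called 0 genes in limma at 8 weeks, with 479 at an unadjusted p under 0.05, and at 10 weeks 3. These were Nos1ap by 1.58 ± 0.29, Cyp8b1 by -3.00 ± 0.56 (adjusted p = 0.0351 each) and the glucuronosyltransferase Ugt1a10 by -1.53 ± 0.26 (adjusted p = 0.0313). At 40 weeks 324 genes had another diet effect, 208 of them a lower one, in irradiated mice. The difference was -3.17 ± 0.48 for Cd36 (adjusted p = 0.000712), 2.47 ± 0.31 for Bhmt (0.000102) and 3.37 ± 0.45 for Sult5a1 (0.000168). These 3 were called under every setting run. Cyp2b10 differed by -5.36 ± 1.15 (adjusted p = 0.0141). Of 20 male-biased genes 6 had a higher diet effect (12 adjusted over the list alone, median 1.21, camera adjusted p = 1.24e-08, adjusted p = 0.729 with an estimated correlation). Of 31 interferon genes 1 had one (6 adjusted over the list alone, median 0.64, camera adjusted p = 2.82e-06, adjusted p = 0.89 with an estimated correlation). The medians were 1.32 and 0.66 with slide as a block, and that of interferon genes was 0.40 without irradiated CR array 2.

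Limma called 1 interaction with slide as a block at 10 weeks and 75 at 40 weeks, and Nos1ap (adjusted p = 0.104), Ugt1a10 (0.104), Cyp8b1 (0.393) and Cyp2b10 (0.112) were lost. The replicate block gave 1 at 8 weeks and 0 at 10 weeks (adjusted p = 0.086 for Nos1ap, Cyp8b1 and Ugt1a10). At 8 weeks the count was 17 without slide 1, 1 without irradiated AL array 1 and 10 without irradiated AL array 3. The 10-week count was 0 without irradiated AL array 1, irradiated CR array 1 or nonirradiated CR array 2, 1 without irradiated AL array 2 or nonirradiated CR array 3. It was 5 and 94 without nonirradiated AL arrays 3 and 1, 10 without irradiated CR array 3 and 113 without irradiated AL array 3. Without nonirradiated CR arrays 2 or 3, irradiated CR array 1 or irradiated AL array 1, Cyp8b1, Nos1ap and Ugt1a10 were lost, with adjusted p-values between 0.0726 and 0.166. So were Cyp8b1 and Nos1ap without nonirradiated AL array 3 (0.0755 and 0.0741) or irradiated AL array 2 (0.0714 each), Cyp8b1 without nonirradiated CR array 1 (0.133), Nos1ap without irradiated CR array 2 (0.0667) and Ugt1a10 without nonirradiated AL array 2 (0.0572). At 40 weeks the count was 768, 602 and 42 without irradiated CR arrays 1, 2 and 3, and 54 and 194 without nonirradiated CR arrays 2 and 3. It was 113 and 101 without nonirradiated AL arrays 1 and 2, and 120, 202 and 157 without irradiated AL arrays 1, 2 and 3. Cyp2b10 was lost without nonirradiated CR array 2 (0.0654) or irradiated CR array 3 (0.0786). Counts were 190 with no filter and 21 with only these groups fitted at 40 weeks. At 10 weeks they were 25 with normexp (12 higher, 13 lower), 2 higher and 2 lower with quantile normalization, 5 with slide as a random block and 0 with only these groups fitted.

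Under AL, 40-week hepatocytes differed from 8-week ones in 1704 genes that were higher and 2043 lower without irradiation, and in 2768 higher and 1725 lower with it. Cyp4a14 rose by 8.76 ± 0.79 and 8.93 ± 0.79 (adjusted p = 1.28e-09 and 8.85e-10), Cyp4a10 by 6.30 ± 0.34 and 6.96 ± 0.34, and Cidec by 4.36 ± 0.58 and 3.74 ± 0.58. Fasn fell by 5.30 ± 0.42 and 5.87 ± 0.42 (adjusted p = 1.44e-10 and 1.57e-11). Of 30 PPARα target genes 26 and 28 rose and 0 and 1 fell (27 and 28 higher adjusted over the list alone, medians 1.33 and 1.63, camera adjusted p = 6.16e-31 and 6.68e-27, 0.00798 and 0.0174 with an estimated correlation). Of 20 fatty acid synthesis genes 16 and 15 fell (18 and 15 adjusted over the list alone, medians -2.08 and -1.92, camera adjusted p = 1.24e-15 and 4.4e-16; adjusted p = 0.0609 and 0.054 with an estimated correlation). Of 23 cholesterol synthesis genes 20 and 19 fell (21 and 19 adjusted over the list alone, medians -1.97 and -1.76, camera adjusted p = 1.6e-18 and 1.17e-18; adjusted p = 0.0676 and 0.0657 with an estimated correlation). Of 18 lipid droplet genes 8 and 11 rose and 2 fell in each (9 and 12 higher, 4 and 2 lower adjusted over the list alone, medians 1.13 and 1.39, camera adjusted p = 0.00838 and 0.00667; adjusted p = 0.161 and 0.163 with an estimated correlation). Of 26 fibrosis and stellate cell markers 4 and 3 rose and 6 and 7 fell (5 and 3 higher, 6 and 7 lower adjusted over the list alone; medians -0.13 and -0.20, camera adjusted p = 0.855 and 0.0978). The collagen gene Col3a1 differed by -2.22 ± 0.51 and -2.27 ± 0.51. Of 17 cytosolic heat shock proteins 6 and 16 rose, over all genes and adjusted over the list alone, and 0 fell (medians 0.37 and 0.72, camera adjusted p = 0.00121 and 6.33e-06; adjusted p = 0.891 and 0.607 with an estimated correlation). The chaperone Hspb1 rose by 2.09 ± 0.38 and 2.20 ± 0.38, and Hspa1a by 3.41 ± 0.78 with irradiation (adjusted p = 0.00147). Of 22 Kupffer cell markers 3 and 6 fell (0 and 6 adjusted over the list alone, medians -0.45 and -0.60, camera adjusted p = 0.183 and 0.00148; adjusted p = 0.739 with an estimated correlation in irradiated mice). Of 19 lymphocyte markers 2 and 4 fell and 1 and 0 rose, over all genes and adjusted over the list alone (medians -0.001 and -0.68, camera adjusted p = 0.878 and 0.00117; adjusted p = 0.607 with an estimated correlation in irradiated mice). Cdkn1a differed by -0.14 ± 0.68 and 1.09 ± 0.68 (adjusted p = 0.906 and 0.228).

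No slide held both ages, and with slide as a block limma called 1.27% of genes without and 1.84% with irradiation. Col3a1 (adjusted p = 0.134 and 0.101), Hspb1 (0.341 and 0.498) and Hspa1a (0.439) were then lost. Cyp4a14, Cyp4a10, Cidec and Fasn were still called. The medians were 1.79 and 2.17 for PPARα targets, -1.59 and -1.45 for fatty acid synthesis, -1.95 and -1.24 for cholesterol synthesis, and 0.81 and 1.84 for lipid droplets (adjusted p = 0.0633 without irradiation). They were 0.32 and 0.45 for heat shock proteins (adjusted p = 0.139 and 0.279), -0.35 and -0.57 for fibrosis markers (0.133 and 0.00635), -1.29 and -1.79 for Kupffer cell markers (3.72e-05 without irradiation) and -1.16 for lymphocyte markers with irradiation. Without irradiated 8-week arrays 1 and 3 the Kupffer cell median was -0.35 and -0.90, and without array 1 the lymphocyte one was -0.33. The Kupffer cell list in nonirradiated mice passed without 40-week array 2 (median -0.57, adjusted p = 0.03). The fibrosis list passed with irradiation also without 8-week array 3 (adjusted p = 0.0146) or 40-week array 2 (0.0202). The fit of only the compared groups called 1790 and 2619 genes, and 2067 were called without irradiation when slide 1 was left out.

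Between 8 and 40 weeks the diet effect rose for 2364 genes and fell for 3048. The change was -8.88 ± 0.79 for Cyp4a14 (adjusted p = 3.08e-10), 7.26 ± 0.42 for Fasn (adjusted p = 3.63e-14), -5.89 ± 0.76 for Cyp7a1 (adjusted p = 3.05e-07) and 3.77 ± 0.68 for Cdkn1a (adjusted p = 5.3e-05). Of 20 fatty acid synthesis genes 17 had a higher effect at 40 weeks, over all genes and adjusted over the list alone (median 2.66, camera adjusted p = 3e-16, 0.0455 with an estimated correlation). Of 30 PPARα targets 23 had a lower one, again in both counts (median -1.37, camera adjusted p = 9.28e-15, adjusted p = 0.0898 with an estimated correlation). Of 22 endothelial markers 12 had a higher one (14 adjusted over the list alone, median 0.54, camera adjusted p = 0.000966, adjusted p = 0.766 with an estimated correlation). Limma called 3020 genes with slide as a block and the medians were 2.71, -1.11 and 0.56.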

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

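The tests of a weaker realised diet restriction, of Cdkn1a against the clock, of the slide for Cdkn1a and of shared control arrays were planned, while the other tests in this part and the comparisons of diet and irradiation effects between ages were chosen after the results were seen. Each result here is listed because the effect in 1 group of mice differed from that in another by an interaction test in limma (n = 3 arrays per group).

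The diet effect at 40 weeks differed with irradiation in 324 genes (2.26% of those tested). Negative values, a smaller rise or larger fall with CR in irradiated mice, were Cyp2b10 (-5.36 ± 1.15), Cyp2b13 (-4.63 ± 1.13, adjusted p = 0.027), Cd36 (-3.17 ± 0.48) and Vldlr (-2.99 ± 0.68, adjusted p = 0.0199). Positive values were Tff3 (3.52 ± 0.88, adjusted p = 0.0303), Bhmt (2.47 ± 0.31), Sult5a1 (3.37 ± 0.45) and Elovl3 (3.29 ± 0.78, adjusted p = 0.0247), and list medians were 1.21 for male-biased and 0.64 for interferon genes (adjusted p = 0.729 and 0.89 with an estimated correlation). Cyp2b9 (-5.14, adjusted p = 0.0301), Slc22a29 (-4.21, adjusted p = 0.00163), Cux2 (-3.69, adjusted p = 0.0133), Cass4 (4.19, adjusted p = 0.00252) and Stap1 (3.50, adjusted p = 0.00252) were also called, but each was well above background on no array of at least 1 of the groups, so these fitted values have no settled size. At 10 weeks 3 genes (0.0209%) differed: Nos1ap (1.58 ± 0.29), Cyp8b1 (-3.00 ± 0.56) and Ugt1a10 (-1.53 ± 0.26). At 40 weeks these calls were lost (adjusted p): without nonirradiated CR array 1 Tff3 (0.0652), Cyp2b9 (0.0572), without nonirradiated CR array 2 Tff3 (0.0799), Cyp2b13 (0.0849), Vldlr (0.0725), Elovl3 (0.0917), Cux2 (0.0659), Cyp2b9 (0.105), without irradiated CR array 3 Tff3 (0.155), Cyp2b13 (0.143), Vldlr (0.1), Elovl3 (0.11), Cyp2b9 (0.156), without nonirradiated AL array 1 Tff3 (0.0802), Vldlr (0.0592), Elovl3 (0.0592), Cyp2b9 (0.0632), without nonirradiated AL array 2 Tff3 (0.0634), Cyp2b13 (0.0726), Cyp2b9 (0.0743), without irradiated AL array 1 Tff3 (0.0579), Vldlr (0.0524), Cyp2b9 (0.0516), without irradiated AL array 3 Tff3 (0.0878), Cyp2b13 (0.0607), Elovl3 (0.051), Cyp2b9 (0.0778), without irradiated AL array 2 Cyp2b13 (0.0521). Stap1 was 0.93 with normexp (0.0616) and Cux2 -0.51 (0.296).

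Redrawing irradiation within each age and diet, 3 of 100 draws gave as many genes as the real 324 at 40 weeks (highest other 361). That share is under 0.05, but the draws ignored slide, and nonirradiated AL arrays lay on slide 3 and 2 of 3 irradiated ones on slide 4. With slide as a block 9 of 100 draws gave as many as the real 75 (highest other 324), so chance is excluded only with no slide term. Without 1 array 0.292 to 5.35% were called. Chance is not excluded at 10 weeks, with 16 of 100 (real 3, highest other 16). At 8 weeks limma called 0 genes (479 at an unadjusted p under 0.05), a count that 100 of 100 draws reach whatever the data, so the draws test nothing there. The highest other, 3198, points to a structure of the samples.

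The irradiation effect under CR at 40 weeks differed from its mean at 8 and 10 weeks in 2.05% of genes, among them Elovl3 (3.37 ± 0.68, adjusted p = 0.00733), Sult5a1 (2.83 ± 0.39, adjusted p = 0.000153) and Bhmt (2.41 ± 0.27, adjusted p = 7.59e-06). Cux2 (-5.08, adjusted p = 0.000104) and Stap1 (3.47, adjusted p = 0.000482) were called without a settled size. Of 100 draws 13 gave as many (highest other 10.5%, a structure of the samples), so chance is not excluded. The percentage was 4.73, 0.807 and 0.466 without irradiated 40-week arrays 1, 2 and 3, 0.515 and 0.773 without nonirradiated 40-week arrays 2 and 3, 1.26 without irradiated 10-week array 3 and 1.27 without irradiated 8-week array 2. Elovl3 had an adjusted p of 0.0854 within slides.

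Irradiated and nonirradiated CR hepatocytes at 40 weeks lay on 1 slide, where limma called 1744 genes, which argues against a slide batch. The irradiated mice may have had a weaker realised restriction: over genes of the 10-week diet effect (262 higher, 375 lower) they lost 40.1% (SE 11.1) of the 40-week diet effect, although this score shares the 3 nonirradiated CR arrays with the comparison. RNA of other cells could add to it and stays open, since the largest gap between the mean shifts of 2 of 7 cell type lists was 2.98 SEs (erythroid 0.77 ± 0.30, cholangiocyte -0.12 ± 0.14). The most abundant erythroid gene, Hba-a2, had mean levels of 9.78 and 10.51 without and with irradiation. A lasting effect of irradiation itself was not separated from these.

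The diet effect differed between 8 and 40 weeks in 5412 genes (37.7%), with Cyp4a14 (-8.88 ± 0.79), Cyp4a10 (-7.24 ± 0.34, adjusted p = 6.52e-16), Fasn (7.26 ± 0.42), Fabp5 (7.59 ± 0.52, adjusted p = 1.66e-12), Cyp7a1 (-5.89 ± 0.76), Cdkn1a (3.77 ± 0.68), Arntl (2.92 ± 0.92, adjusted p = 0.0125) and Col3a1 (2.99 ± 0.52, adjusted p = 2.8e-05). List medians were -1.37 for PPARα targets (adjusted p = 0.0898 with an estimated correlation), 2.66 for fatty acid synthesis (0.0455) and -1.01 for pericentral genes, of which 12 of 19 fell (12 adjusted over the list alone, camera adjusted p = 5.89e-06, 0.0427 with an estimated correlation). The endothelial median was 0.54 (adjusted p = 0.766 with an estimated correlation). Of 100 redraws of age 1, the real one, called as many genes (highest other 4024), which excludes chance. These redraws ignored slide, and no slide held both ages. With slide as a block 3020 genes (21%) were called, again the most of 100 draws (highest other 2704), and redraws that call 28% point to a structure of the samples. Between 8 and 10 weeks Cdkn1a (3.89 ± 0.68, adjusted p = 0.000406) and Saa1 (-4.06 ± 0.91, adjusted p = 0.00411) differed, as did Moxd1 (-5.75, adjusted p = 0.000788) without a settled size, Saa1 with an adjusted p of 0.0859 with slide as a block.

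AL hepatocytes at 40 weeks may have shifted toward the 8-week CR state. A slide batch as the whole cause is argued against, since at least 76.1% of the list medians was kept with slide as a block (PPARα targets 1.48 to 1.98, fatty acid synthesis -2.002 to -1.52), and shared arrays too, since age and diet effects that share none correlate at 0.52 and 0.557 over 14368 genes. The clock score of AL arrays differed by 0.52 (SE 1.03) between the ages against 6.09 with diet at 10 weeks. It differed by 1.84 (SE 0.81) without nonirradiated 8-week array 2, whose score was 0.03 against -8.33 to -7.39 on other 8-week AL arrays. So a clock state that differs with age stays open, as do feeding state at collection (not given) and age.

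Cdkn1a may follow the clock state of the liver in part. Its within-slide diet effect at 10 weeks, 5.92 (SE 0.76) without irradiation, argues against a slide batch. With the clock score as a covariate the diet effect at 10 and 40 weeks was 2.24 ± 0.31 against 4.96 ± 0.36. It lay 7.17 SEs above 0, which by a criterion set afterwards argues against the clock state as the whole cause. On the AL arrays with scores of 0.03 and 0.18 Cdkn1a lay at 0.31 and 0.79, against 2.39 to 4.19 on CR arrays at 10 and 40 weeks (scores -0.96 to 1.75). How much follows the clock stays open, as the hour of collection is not given. Over 42 arrays, as deviations from group means, r was 0.891 and rho 0.819 (permutation p = 1e-05 each, the smallest possible). A slide block gave r 0.882, and slides 2 to 5 (7, 6, 8 and 6 arrays) 0.811, 0.806, 0.758 and 0.79. Without the 2 farthest arrays r was 0.792, from group means that held them.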

How the results depend on the processing

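Leaving out slide 1 or single ages and groups, and every alternative for effects compared between ages, came after the data were seen. The others were planned. Among the settings run no call changed direction. With the submitters' values each of the 22 counts stayed within 1.5 times and each of the gene and list results run kept its side of the threshold. Those values differ from the scaled ones used here only by probe centring, which cancels in every comparison. This outcome was fixed in advance and tests no other processing. Single-gene calls were lost in 31 cases with normexp (1 gained), 3 with quantile normalization, 10 with no filter, 85 with slide as a fixed and 17 as a random block, 40 of 160 within slides, 13 with the replicate block, and 238 of 3060 cases without 1 array (5 gained). Lists lost their call in 4, 1, 2, 6 (2 gained), 0, 2 of 64 and 2 cases in the same order, in 10 of 1146 without 1 array (6 gained) and in 69 with an estimated correlation.

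Counts that moved over 1.5 times are given as percent of the genes tested, and causes were not tested unless named. For irradiation under AL at 8, 10 and 40 weeks (0.452, 0.104 and 0.00696) they were 0.146, 0.237 and 0.0209 with normexp, 1.76, 0.16 and 0 with quantile normalization, 0.49, 0.0388 and 0 with no filter, 0.00696, 0.0139 and 0.0139 with slide as a fixed block and 0.0278, 0.00696 and 0.0278 within slides. At 8 and 40 weeks they were 0.0557 and 0 with slide as a random block and 0.933 and 0 with the replicate block. For irradiation under CR at 8 and 10 weeks (0.202 and 0.0974) they were 0 and 0.0209 with normexp, 0 and 0.0209 with slide as a fixed and 0.0418 and 0.0209 as a random block and 0.411 and 0.0278 with the replicate block, then 0.538 at 8 weeks with no filter, and 0.23 and 0.0209 at 10 weeks with quantile normalization and within slides. At 7 weeks (0.0139) quantile normalization gave 0.0348. The mean irradiation effect (3.42) gave 1.56 with no filter, 0.104, 1.29 and 0.16 with slide as a fixed block, a random block and within slides, 0.599 without slide 1, 1.02 without the CR groups at 40 weeks and 2.1 without the 8-week groups.

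With slide as a fixed block the values were 7.49 for diet in nonirradiated mice at 40 weeks (28.9), 4.17 in irradiated mice at 10 weeks (23.1), 29.5 for its mean (47.2), 1.27 and 1.84 for age without and with irradiation (26.1 and 31.3) and 21 for diet between ages (37.7). Interactions at 10 and 40 weeks (0.0209 and 2.26) gave 0.00696 and 0.522 with that block, 0.174, 0.0348 and 0 at 10 weeks with normexp, a random block and the replicate block, and 0.922 at 40 weeks with no filter. At 8 weeks limma called 0 (479 genes at an unadjusted p under 0.05), 0.00696 with the replicate block and 0.118 without slide 1. Irradiation under CR between ages (2.05) gave 0.839 with no filter, 1.26 with the block and 0.891 within slides. Without slide 1 irradiation under AL at 8 weeks had 0.0209, diet in nonirradiated mice at 8 weeks (17.2) 4.93 and age without irradiation 14.4.

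Fits of only the compared groups estimate the spread from fewer arrays. They called 0% of genes for irradiation at 7 weeks, 0, 0 and 0 under AL and 0.00696, 0 and 0.0766 under CR at 8, 10 and 40 weeks, 3.67 and 15.1 for diet in nonirradiated mice at 8 and 10 weeks, 8.85 and 5.61 in irradiated mice at 8 and 40 weeks, 12.5 and 18.2 for age, 0 and 0.146 for interactions at 10 and 40 weeks and 0.612 for irradiation under CR between ages.

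Without 1 array, which leaves 2 in its group, the percent called ranged over 0 to 0.0139 for irradiation at 7 weeks, 0.0487 to 13.3, 0.00696 to 0.786 and 0 to 0.0209 under AL at 8, 10 and 40 weeks, 0.0278 to 4.06, 0 to 0.0766 and 2.84 to 14.3 under CR, 2.18 to 9.52 for its mean, 12.1 to 26.6 for diet in irradiated mice at 40 weeks, 0 to 0.0696, 0 to 0.786 and 0.292 to 5.35 for interactions and 0.466 to 4.73 for irradiation under CR between ages. Genes below background in a group have only a bound. The fitted value of Fut4 under AL at 8 weeks was -1.96 and -0.14 with normexp, which also used another signal column and an offset of 50. With no filter on dim probes the median of all genes moved to -0.148 and -0.139 for irradiation under AL and CR at 8 weeks and -0.221 for age without irradiation.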

Other observations

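The tests of gene lists under diet were planned, and the other tests in this part were chosen after the results were seen. Averaged over the diet comparisons CR raised 31 of 33 cytosolic ribosomal protein genes (32 adjusted over the list alone, median 0.26, camera adjusted p = 8.19e-12, adjusted p = 0.212 with an estimated correlation) and lowered 12 of 22 Kupffer cell and macrophage markers (15 adjusted over the list alone, median -0.35, camera adjusted p = 0.00193, adjusted p = 0.471 with an estimated correlation), with medians of 0.29 and -0.53 with slide as a block. Of 28 hepatocellular carcinoma and fetal liver genes 8 rose and 9 fell, over all genes and adjusted over the list alone (median -0.05, camera adjusted p = 0.369). Of 19 DNA repair genes 3 and 1 rose and 6 and 9 fell with CR at 40 weeks in nonirradiated and irradiated mice (3 and 1 higher, 6 and 12 lower adjusted over the list alone, medians -0.12 and -0.41, camera adjusted p = 0.275 and 0.00136; adjusted p = 0.389 with an estimated correlation in irradiated mice), and the nonirradiated median was 0.01 with slide as a block.

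Irradiation may raise interferon response genes at each age and diet. Their median was above 0 in 7 of 7 irradiation comparisons and in 6 with slide as a block, and an exact sign-flip test of the list means gave p = 0.0156, the smallest that 128 flips can give, or 0.544 adjusted over 38 lists, so the hypothesis stays open.

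The irradiation effect under CR could be partly shared between 10 and 40 weeks. Over genes the 2 effects, which share no arrays, correlate at 0.341 (0.229 with slide as a block), and 4 of 100 pairings of splits of the same arrays reached that size, the real one included. The highest other, 0.406, lay above it. With slide as a block 6 of 100 pairings did (highest other 0.306). The 8-week effect correlates with those at 10 and 40 weeks at 0.168 and 0.122, and the largest of the 3 correlations was reached in 5 of 100 draws of splits at all 3 ages, so chance is not excluded.

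With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real percent of genes called (highest other split) was 0.0139 (0) for irradiation at 7 weeks, 0.452 (12.4), 0.104 (1.2) and 0.00696 (0.00696) under AL at 8, 10 and 40 weeks and 0.202 (0.264), 0.0974 (0.00696) and 10.9 (0.139) under CR, with 1, 4, 3, 2, 2, 1 and 1 splits as large. Highest splits of 12.4 and 1.2 point to a structure of the samples. For diet at 8, 10 and 40 weeks it was 17.2 (6.43), 27.2 (0.0139) and 28.9 (0.00696) in nonirradiated and 20 (0.139), 23.1 (0.0139) and 23.2 (0.0418) in irradiated mice, and 26.1 (0.0209) and 31.3 (0.0487) for age, with 1 split as large in each. For the mean effects of irradiation and diet 1 of 100 draws each was as large, 3.42 (1.59) and 47.2 (3.87), which excludes chance. These draws ignored slide. With slide as a block 1 of 100 was as large too, 0.104 (0.0766) and 29.5 (6.2).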
